A study of Mus musculus with 47 samples.

How the data were processed

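The data were 3' tag libraries (SOLiD SAGE) from 12 male C57BL/6J mice, housed at 23 C and fed a control or a methionine-restricted diet for 11 weeks from 5 weeks of age. Per the labels, each library was made from 7 to 12 ng of total RNA, and fragments that mapped to a single place among mouse RefSeq genes were kept. The aligner and the counting tool are not given in the sources used here. The deposited raw tables held the count of tags for each gene symbol and library, as whole numbers with no normalization, with 1 table per tissue and 26608 genes in each. The authors also deposited a normalized signal for each gene and library, made with DESeq, whose version is not given in the sources used here. On the values, this signal was the raw count divided by 1 size factor per library, and it held only genes with a total raw count of at least 20 in the tissue (15 in gastrocnemius). The raw counts were used for the main analysis and the normalized signal for alternatives. In the raw counts of gastrocnemius, 25 gene symbols had the form of dates, so the joint fit used the 26583 symbols held by all 4 tables. Animal MR3113 had no gastrocnemius library in the files used.

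Depth, as the sum of counts per library, ran from 4887004 to 13117537. For a gene with 0 counts, 3 counts were taken as the upper limit, which is 0.229 to 0.614 CPM by library and covers counting error only, not the spread between animals. Each tissue was analysed on its own. Genes were kept with filterByExpr at its defaults (minimum count of 10), and libraries were scaled with TMM factors. Diets were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The kept genes held between 99.6 and 99.8 percent of the counts in each tissue. CPM and log2 CPM used a prior count of 2 on the log scale. Values are given as mean ± SD over animals or log2 fold change ± SE, with each animal as a replicate. The SE was worked back from the F test, as the absolute log2 fold change divided by the square root of F.

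Named genes followed a rule fixed before the data were examined. In each tissue these were the 10 largest increases and the 10 largest decreases past the threshold. They needed a mean of at least 20 raw counts in the higher group and every restricted library on the same side of the control mean, and predicted genes without a proper name were counted but not named. Up to 4 members with the smallest p were named for each described list, with 8 genes chosen in advance (Fgf21, Scd1, Ucp1, Asns, Phgdh, Psat1, Lep and Igf1). For the interaction, the 6 genes with the smallest adjusted p and list members among the leading 100 were named. Genes called in more than 1 tissue were also named, which was decided after the data were seen, since the fixed rule asked for at least 3 tissues. The result of 1 gene that the rule would name is not reported here. The 30 gene lists, the tests and most alternatives were also fixed before the data were examined.

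Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values, with its preset correlation of 0.01 and adjustment over all 116 tests together. Camera with an estimated correlation and fry were run beside it, and members were also adjusted over their list alone. Members were matched by symbol, so a gene listed under a symbol that the counts do not use was not tested as a member. Some lists mark cell types, and a list name does not say that the cells were present. The difference of the diet effect between tissues was tested in 1 edgeR fit of all 47 libraries with terms for tissue, diet and their interaction, over the 4 tissues together and for 3 pairs, and the other 3 pairs were tested in the same fit for named genes. The animal was not a term in this fit. A fit with the animal as a replicate block was an alternative, since the tissues came from the same animals. Within a tissue each animal gave 1 library and nothing could be blocked.

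The pairing of libraries by animal was checked on the data. The mean correlation of deviations from the diet mean between libraries of the same animal was between -0.076 and 0.063 over the 6 pairs of tissues, and the correlation estimated by limma for the block was -0.0325. For IWAT and liver the mean was 0.063, against -0.012 between different animals of the same diet. In that pair 7 of 12 animals correlated best with their own library, and 1 to 4 did in the other pairs. Sharing by animal is thus not excluded for IWAT and liver. Libraries stood apart when their median Spearman correlation to the other libraries of the tissue was under 0.8, which held for CON3106, CON3115 and MR3116 in IWAT and MR3101 in gastrocnemius. None was removed from the main analysis. Tag GC content was taken from the 23 bases after the NlaIII site nearest the 3' end of protein-coding transcripts (GENCODE vM1), and coordinates from RefSeq genes on GRCm38, the assembly that the labels name.

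Alternatives were DESeq2 1.42.0, limma voom, other scaling factors, no filter or a mean of at least 50 counts, the deposited normalized signal with pseudocounts of 1 and 8, 1 fit over all libraries, marker levels as covariates, and each library or animal left out. Leaving out or modelling the libraries that stood apart, leaving out animals other than MR3113 in the joint fit, leaving out animals for the shared genes, and Spearman correlations of diet effects were chosen after the data were seen. Diets were also reassigned to whole animals in 100 ways with a fixed seed, the real assignment included. Figures were made with matplotlib 3.10.9 in Python 3.11.15. The main test was tested on simulated data drawn from the means, dispersions and library sizes of each tissue, with no diet effect but for 200 changed genes. It found 26 percent of 4-fold changes in IWAT, 91 in BAT, 100 in liver and 27 in gastrocnemius, and 1, 39, 77 and 0 percent of 2-fold changes. It called 27, 139, 188 and 28 genes, of which 0, 9, 11 and 1 were false. Each gene was drawn on its own, so the simulated libraries lack the shared deviations of those that stood apart. The shares found and the false calls in the real IWAT and gastrocnemius data may therefore differ.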

Results

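From 5 weeks of age, 12 male mice of the inbred C57BL/6J strain received either a control diet or a diet restricted in the essential amino acid methionine, 6 mice per diet, over a period of 11 weeks. RNA was taken after a 5 h fast from inguinal white adipose tissue (IWAT), interscapular brown adipose tissue (BAT), liver and gastrocnemius muscle of the same animals. Libraries and animals are named by diet and animal number, with CON for control and MR for methionine-restricted. Each tissue gave 6 control and 6 restricted libraries, except gastrocnemius, where 5 restricted libraries were analysed, for 47 libraries in 8 groups. The libraries held short tags from the 3' ends of transcripts, and each deposited value was the number of tags assigned to a gene. Library totals were 4887004 to 7094761 tags in IWAT, 5252688 to 13117537 in BAT, 7710740 to 12130444 in liver and 7756320 to 12829112 in gastrocnemius. Between 11144 and 16406 genes were detected per library. A count of 0 allows up to 0.229 to 0.614 CPM (counts scaled to the size of the library), depending on the library, for counting error only. The question was how the transcripts of each tissue differed between the diets and whether the difference depended on the tissue.

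In IWAT, the lists of the thermogenic program of brown and beige adipocytes, of the respiratory chain and of fatty acid oxidation ranked higher under methionine restriction in camera with its preset correlation, and the matrix list ranked lower. None of their members passed over all genes in edgeR, and the 4 calls were lost with an estimated correlation (camera adjusted p = 0.109, 0.109, 0.292 and 0.0679). As many lists were called in IWAT in 22 of 100 assignments of the diets to the animals, the real one included. The median log2 fold change was 1.96 over the 22 tested thermogenic genes, 1.07 over 45 genes of oxidative phosphorylation and 1.29 over 27 genes of fatty acid oxidation, against -0.98 over 32 matrix genes. Ucp1, which uncouples respiration from ATP synthesis in brown fat mitochondria (chromosome 8, 83290348 to 83298456, GRCm38), had a log2 fold change of 3.15 ± 0.64 (SE, n = 6 and 6) that missed the threshold over all genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.107). Of single genes, Acsl5, an acyl-CoA synthetase (chromosome 19, 55251861 to 55296628), rose from 203 ± 66.8 to 1022 ± 353 CPM (SD, n = 6 and 6). Lbp, the gene of the lipopolysaccharide-binding protein (chromosome 2, 158306493 to 158332852), fell from 310 ± 143 to 43.5 ± 15.9 CPM.

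Of 11101 genes tested in IWAT, 1 was higher and 2 were lower under restriction in the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of all genes, 975 had an unadjusted p under 0.05, where 555 were expected by chance. The log2 fold changes were 2.33 ± 0.32 (SE) for Acsl5, -2.83 ± 0.38 for Lbp and -3.49 ± 0.46 for D3Bwg0562e, each with an adjusted p of 0.0253. D3Bwg0562e averaged 3.83 tags per restricted library, and its log2 fold change ran from -3.69 to -2.01 over the alternatives. Each of the 3 lost its call without any single library other than CON3114 or MR3116, with edgeR adjusted p-values of 0.0590 to 0.130 for Acsl5, 0.0544 to 0.111 for Lbp and 0.0512 to 0.111 for D3Bwg0562e. Leptin (Lep), the adipocyte hormone that reports fat stores, had a log2 fold change of -2.71 ± 1.04 with an adjusted p of 0.405 in edgeR. Igf1 had -0.90 ± 0.31 with an edgeR adjusted p of 0.334. Scd1, Asns, Psat1 and Phgdh had log2 fold changes of -0.33, 0.34, -0.66 and -0.71, none past the threshold, and Fgf21 had too few tags to be tested, with at most 17 in a library.

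Among the lists in IWAT, none of the 22 thermogenic genes passed over all genes, and 17 were higher when adjusted over the list alone. These included Cox8b (2.23 ± 0.37), Letmd1 (2.09 ± 0.39) and the potassium channel gene Kcnk3 (1.57 ± 0.32). The list as a whole ranked above the other genes in camera (adjusted p = 2.49e-22; adjusted p = 0.109 with an estimated correlation). Of 45 oxidative phosphorylation genes, 0 passed over all genes and 12 were higher when adjusted over the list alone, among them Atp5b (1.24 ± 0.29) and Cox4i1 (1.13 ± 0.30). The list had a camera adjusted p of 1.1e-18 and an adjusted p = 0.109 with an estimated correlation. For fatty acid oxidation, 8 of 27 genes were higher and 1 was lower adjusted over the list alone. They were led by the carnitine carrier gene Slc25a20 (1.72 ± 0.33) and Hadhb (2.03 ± 0.41), which acts in mitochondrial beta-oxidation (camera adjusted p = 2.1e-07; adjusted p = 0.292 with an estimated correlation). In the matrix list, 13 of 32 genes were lower adjusted over the list alone, including the collagen genes Col3a1 (-1.94 ± 0.37) and Col6a2 (-1.60 ± 0.37). The list ranked below the other genes (camera adjusted p = 3.04e-14; adjusted p = 0.0679 with an estimated correlation).

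Other lists in IWAT held fewer members past the threshold. White adipocyte markers had a median of -0.84 over 11 genes, of which 2, Ednra (-1.38) and Mest (-2.20), were lower adjusted over the list alone (camera adjusted p = 0.00544; adjusted p = 0.488 with an estimated correlation). The list lost its call without MR3116 (camera adjusted p = 0.119). Macrophage markers had a median of -0.35 over 21 genes, with Emr1 at -1.18 and no member past the threshold over the list alone (camera adjusted p = 0.0139; adjusted p = 0.488 with an estimated correlation). Camera gave adjusted p-values of 0.169, 0.127, 0.0926 and 0.217 without CON3107, MR3101, MR3109 and MR3116. The median of the macrophage list changed sign without CON3107 (0.16) and was -0.83 with the lymphocyte marker level as a covariate, so its direction is uncertain. Lipogenesis genes had a median of 0.68 over 25 genes, led by Gpam at 1.52, and lymphocyte markers 0.42 over 19 genes. They had camera adjusted p-values of 0.00128 and 0.00241, and adjusted p = 0.527 and 0.603 with an estimated correlation. CON3107 had a mean of 7.02 log2 CPM for the lymphocyte markers, and the next control library 2.17. The median of the lymphocyte list was 3.83 without CON3107 and 0.01 with the lymphocyte level as a covariate, and its call was lost with that covariate (camera adjusted p = 0.585) and with the blood marker level (0.0543). The lymphocyte level is the mean of the same list, so the loss with it was set in advance. Cholesterol synthesis genes had a median of 0.35 over 23 genes (camera adjusted p = 0.0262; adjusted p = 0.556 with an estimated correlation). Camera gave 0.0699, 0.127, 0.0503 and 0.0641 without CON3106, CON3107, CON3115 and MR3113, and 0.0699 with no filter. No member of these 3 lists passed adjusted over the list alone.

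Some IWAT libraries stood apart from the rest, and the count of called genes depended on how they were treated. CON3106, CON3115 and MR3116 had median Spearman correlations to the other IWAT libraries of 0.628, 0.719 and 0.647, against 0.857 to 0.914 for the other 9. Alternatives chosen after seeing the data gave 0 genes without these 3 libraries in edgeR, with 1826 genes at an unadjusted p under 0.05, and 315 higher and 305 lower with a term for them in the fit. The thermogenic list had a median of 1.58, oxidative phosphorylation 0.88, the matrix list -0.90 and cholesterol synthesis 0.11 without them. DESeq2 called 168 genes higher and 142 lower, limma voom 5 and 2, edgeR with upper-quartile factors 3 and 3, and limma on the authors' normalized counts 9 and 5 or 10 and 10, by pseudocount. A fit with the blood marker level as a covariate called 565 and 478, and a joint fit over all 47 libraries 266 and 180. The blood marker level was itself far lower in MR3116 (-0.102 log2 CPM) than in the next restricted library (1.965), so that covariate may in part stand for MR3116. The edgeR count was 28 higher and 13 lower without CON3114, 2 and 2 without MR3116, and 0 and 0 without any other single library.

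**Figure D1:**
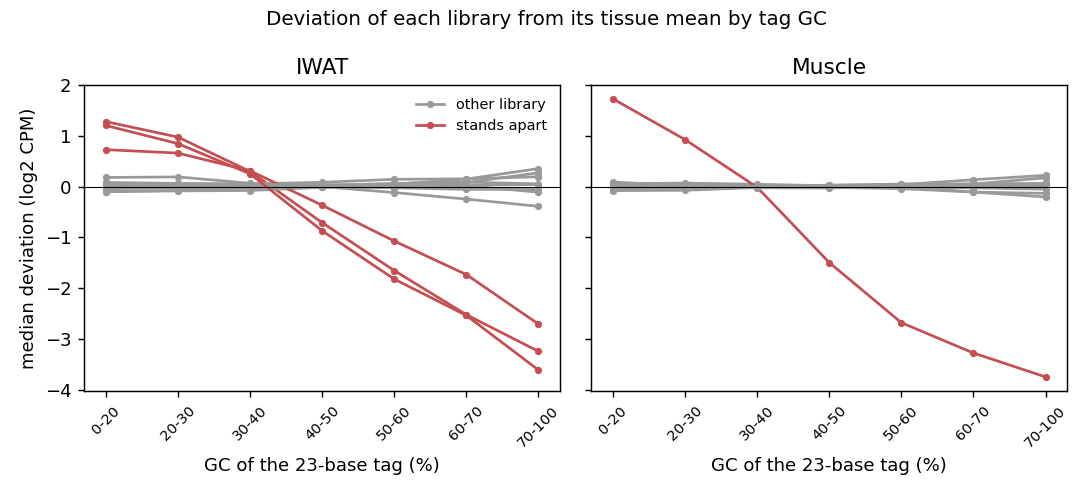
Median deviation of each library from the mean of its tissue, in log2 CPM, by class of GC content of the tag in percent, with a line per library, IWAT on one panel and gastrocnemius on the other. The 4 libraries that stood apart (red) slope down with tag GC, with correlations across genes of -0.485, -0.447 and -0.474 for CON3106, CON3115 and MR3116 in IWAT and -0.476 for MR3101 in gastrocnemius.

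In BAT, 3 of 22 tested thermogenic genes rose and the transcript of leptin fell under methionine restriction. The thermogenic list ranked higher in camera with its preset correlation (adjusted p = 0.000114) and not with an estimated correlation (adjusted p = 0.488). The type 2 deiodinase gene Dio2, which activates thyroid hormone, rose by 1.31 ± 0.25 on the log2 scale (SE, n = 6 and 6). Elovl3, a fatty acid elongase of brown fat (chromosome 19, 46131897 to 46135694), rose by 1.43 ± 0.25. Glycerol kinase (Gyk, also named Gk; chromosome X, 85701937 to 85776819) rose from 125 ± 16.2 to 462 ± 212 CPM (SD). It is in the thermogenic list under the symbol Gk, which the counts do not use, so it is not among the 22 tested genes. Bmp8b, which codes for a secreted factor of brown adipocytes, rose from 0.640 ± 0.329 to 5.60 ± 3.27 CPM. Lep (chromosome 6, 29060221 to 29073876) fell from 26.7 ± 19.5 to 4.81 ± 3.21 CPM, and the desaturase gene Scd1 (chromosome 19, 44394450 to 44407709) fell by 0.97 ± 0.18. The macrophage and matrix lists ranked lower in camera with its preset correlation and not with an estimated correlation (camera adjusted p = 0.488 and 0.453), and the only matrix gene that passed, Loxl1, rose. Dio2 lost its call without CON3107 (edgeR adjusted p = 0.0503), Scd1 without MR3104 (0.0562), and Lep, with edgeR adjusted p-values of 0.0510 to 0.0810, without any single library other than CON3103, CON3107 or CON3112 or MR3102.

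Of 10791 genes tested in BAT, 62 were higher and 58 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 108 also met the rule for naming. The genes with the largest increases were Mfsd2a, a transporter of lysophosphatidylcholine (log2 fold change 4.11 ± 0.70), Bmp8b (3.09 ± 0.41), the purine enzyme gene Gmpr (2.33 ± 0.27), Isyna1, which makes inositol phosphate (2.31 ± 0.24), Foxq1 (2.17), Sgk2 (2.12), Gyk (1.88 ± 0.26), Ttc25 (1.72), Nradd (1.68) and Myrip (1.66). The largest decreases were in Ptgds, a prostaglandin D synthase (-2.79 ± 0.36), Tmem45b (-2.63 ± 0.27), Lctl (-2.62 ± 0.24), Lep (-2.46 ± 0.50), Hspa12a (-2.24), Myo5c (-2.07), Nek6 (-1.96), the monocarboxylate transporter gene Slc16a7 (-1.90 ± 0.24), Mgst2 (-1.88) and Chn1 (-1.81). Their edgeR adjusted p-values ran from 0.000327 for Lctl to 0.0380 for Myrip, and every restricted library lay on the same side of the control mean for each of these genes. Mfsd2a averaged 2.17 tags per control library, and its log2 fold change ran from 1.94 to 5.48 over the alternatives, so its size is uncertain. Bmp8b averaged 6 tags per control library, with 1.92 to 3.27 over the alternatives. Ucp1 had a log2 fold change of 0.86 ± 0.21 and an adjusted p of 0.0717, and Asns, Psat1 and Igf1 had 0.24, -0.53 and -0.38, none past the edgeR threshold.

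Some of these BAT calls rested on single libraries. Nek6 was lost without MR3104 (edgeR adjusted p = 0.0521), and Lep without 8 libraries (0.0510 to 0.0810). Mgst2 was lost without CON3112 and MR3101, MR3102 and MR3104 (edgeR adjusted p of 0.0576 to 0.0585), and Sgk2 without CON3103, CON3114 and CON3115 and MR3104 (0.0510 to 0.0758). Foxq1 was lost without CON3107 and CON3112 and MR3101, MR3104 and MR3116 (edgeR adjusted p of 0.0502 to 0.0679). Nradd was lost without CON3103, CON3106, CON3107, CON3112 and CON3114 and MR3101 and MR3104 (0.0608 to 0.0795), and Myrip without any single library other than CON3103 or CON3106 or MR3113 (0.0577 to 0.0856).

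Of 22 thermogenic genes in BAT, 3 rose over all genes, Elovl3, Dio2 and Kcnk3 (0.85 ± 0.18), and Ppargc1a, a transcriptional coactivator of mitochondrial genes, reached 0.77 with an edgeR adjusted p of 0.0512. Adjusted over the list alone, 6 were higher and 1 lower, and the list had a median of 0.27 and ranked above the other genes in camera (adjusted p = 0.000114; adjusted p = 0.488 with an estimated correlation). Kcnk3 lost its call without any single library other than CON3107 or MR3102 (edgeR adjusted p of 0.0673 to 0.103), and Dio2 without CON3107 (0.0503). In the lipogenesis list, which did not pass as a list (camera adjusted p = 0.378), Gpam, the first acyltransferase of glycerolipid synthesis, rose by 1.29 while Scd1 and the acetyl-CoA synthetase gene Acss2 fell by 0.97 and 0.89. Acss2 lost its call without CON3103, CON3106, CON3107, CON3112 and CON3114 and MR3102, MR3104 and MR3116 (edgeR adjusted p of 0.0523 to 0.0884), and Scd1 without MR3104 (0.0562). Macrophage markers had a median of -0.93 over 18 genes. None passed over all genes in edgeR, and 11 were lower adjusted over the list alone, with Ctss at -1.94 and Ccl6 at -1.62 (camera adjusted p = 8.54e-08; adjusted p = 0.488 with an estimated correlation). The median was -0.49 without CON3106. Of 31 matrix genes, 1 passed, Loxl1, and it rose (1.08 ± 0.20). The list had a median of -0.56, with 3 genes lower and 1 higher adjusted over the list alone, and ranked lower (camera adjusted p = 1e-06; adjusted p = 0.453 with an estimated correlation). Without CON3103, CON3112 and CON3114, Loxl1 had edgeR adjusted p-values of 0.0521, 0.0542 and 0.0552.

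White adipocyte markers in BAT had a median of -0.70 over 8 genes, of which Lep fell over all genes and 3 were lower adjusted over the list alone (camera adjusted p = 0.0220; adjusted p = 0.512 with an estimated correlation). The camera adjusted p of this list was 0.182 without CON3106, where its median was -0.23, and 0.0598 with the stricter filter, and Lep was lost without 8 libraries. Cholesterol synthesis genes had a median of 0.19 over 23 genes, with 2 higher adjusted over the list alone, among them Sc4mol (0.81). It had a camera adjusted p of 0.0206 and an adjusted p = 0.512 with an estimated correlation. That list lost its call without CON3112 (camera adjusted p = 0.0741) and MR3102 (0.0659) and with the stricter filter (0.0572). Its median ran from 0.11 without MR3113 to 0.25 without MR3102.

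Other lists in BAT went with particular libraries or with members that do not act in this tissue as the list name says. The list of liver genes higher in females had a median of -0.50 over 6 genes, of which 1 fell, the peroxisomal transporter gene Abcd2 (-1.31 ± 0.18). Adjusted over the list alone, 3 were lower (camera adjusted p = 0.0124; adjusted p = 0.221 with an estimated correlation). The list of muscle atrophy genes had a median of 0.17 over 18 genes, with 2 higher adjusted over the list alone, Bnip3 (0.84) and Mt2 (1.33), a camera adjusted p of 0.0248 and an adjusted p = 0.488 with an estimated correlation. It lost its call without CON3103 (camera adjusted p = 0.0895) and CON3115 (0.148) and with the skeletal muscle marker level as a covariate (0.208). The median of the atrophy list was 0.04 without MR3109. Hepatocyte markers had a median of -1.55 over 10 genes, with Apoa1 at -4.38 and Alb at -3.69. It had 7 members lower adjusted over the list alone, a camera adjusted p of 0.00763 and an adjusted p = 0.576 with an estimated correlation. CON3106 had a mean of 7.38 log2 CPM for the hepatocyte list and the next BAT control 3.91, and without CON3106 the camera adjusted p was 0.175, the median of the list -0.22, and Apoa1 and Alb were at -0.08 and -0.37. For skeletal muscle markers, camera ranked the list higher (adjusted p = 0.0397; adjusted p = 0.777 with an estimated correlation) while its median (-0.67) and mean (-0.69) over 25 genes were below 0. That call was lost without any single library other than CON3106, CON3112 or CON3114 or MR3104, with camera adjusted p-values of 0.0549 to 0.565. It was also lost with the stricter filter (0.0572), on the authors' normalized counts with a pseudocount of 8 (0.0687) and with the list's own level as a covariate (0.654). The last of these was set in advance, since the covariate is the mean of the list itself. The median ran from -0.99 to 1.16 over the alternatives, so the direction of this list is uncertain. The mean level of the list ran from 1.90 log2 CPM in CON3115 to 9.42 in CON3112, and from 3.60 to 7.96 across the restricted libraries.

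The BAT counts moved with the test and with single libraries. DESeq2 called 165 genes higher and 152 lower, a joint fit over all 47 libraries 22 and 19, and a fit with the skeletal muscle marker level as a covariate 94 and 97. The edgeR counts were 34 and 37 without CON3103, 31 and 35 without CON3112, 28 and 35 without CON3114, 33 and 33 without MR3101, 41 and 38 without MR3102, and 25 and 25 without MR3104.

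**Figure D2:**
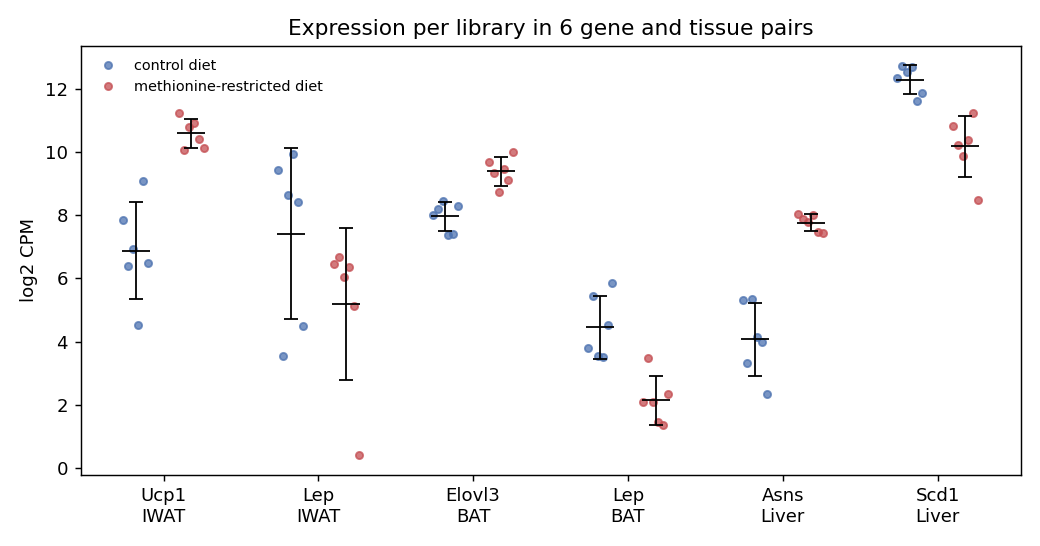
Expression of 6 gene and tissue pairs in log2 CPM, with a point per library, control in blue and methionine-restricted in red, and bars for the mean and SD (n = 6 per diet). The restricted libraries lie above all control libraries for Ucp1 in IWAT (edgeR adjusted p = 0.107), Elovl3 in BAT and Asns in liver. They lie below all control libraries for Lep in BAT and Scd1 in liver. Lep in IWAT shows overlapping groups, with an edgeR adjusted p of 0.405. The overlap comes from CON3106 (3.54) and CON3115 (4.50), control libraries that stood apart.

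In liver, 8 of 24 genes that respond to a shortage of amino acids and 8 of 28 NRF2 targets rose, while 7 of 24 lipogenesis genes and 6 of 25 liver genes higher in males fell, and 1 NRF2 target, Gstm6, fell. With an estimated correlation, camera called the amino acid list (adjusted p = 0.0213) and not the other 3 (adjusted p = 0.165, 0.292 and 0.278). Asns, the asparagine synthetase gene (chromosome 6, 7675165 to 7693209), rose from 21.4 ± 15.2 to 221 ± 38.6 CPM (SD, n = 6 and 6). Psat1, which acts in serine synthesis (chromosome 19, 15905123 to 15925059), rose from 2.76 ± 1.94 to 21.9 ± 8.20 CPM. Fgf21, the gene of a hormone secreted by the liver (chromosome 7, 45613890 to 45615490), rose by 1.76 ± 0.35 on the log2 scale (SE). Csad, an enzyme gene of taurine synthesis, rose from 25.5 ± 6.86 to 152 ± 30.1 CPM. Scd1 fell by 1.95 ± 0.35.

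Of 10969 genes tested in liver, 115 were higher and 133 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 217 met the rule for naming. The largest increases were in Asns (3.37 ± 0.41), the mitochondrial folate enzyme gene Aldh1l2 (3.15 ± 0.33), Psat1 (2.99 ± 0.37), the villin gene Vil1 (2.91 ± 0.24), the fatty acid hydroxylase gene Cyp4a14 (2.88 ± 0.24), Csad (2.58 ± 0.18), AB056442 (2.40), Dnaic1 (2.31), Cyp2c69 (2.21) and the oxysterol hydroxylase gene Cyp39a1 (2.15 ± 0.22). The largest decreases were in Cml3 (-5.22 ± 0.58), the acetylcholine receptor gene Chrna4 (-4.24 ± 0.63), Dct (-3.62 ± 0.38), Scara5 (-3.36), the trehalase gene Treh (-3.19), the aquaporin gene Aqp4 (-2.64 ± 0.33), the acute phase gene Saa1 (-2.59 ± 0.62), Dntt (-2.53), Cyp4a12b (-2.42 ± 0.37) and the glypican gene Gpc1 (-2.41). Every restricted library lay on the same side of the control mean for each, and the edgeR adjusted p-values ran from 4.53e-06 for Csad to 0.0414 for Saa1. Saa1 lost its call without CON3106 and CON3107 and MR3101, MR3104, MR3109, MR3113 and MR3116 (edgeR adjusted p of 0.0799 to 0.0982), and AB056442 without CON3106, CON3112 and CON3114 and MR3109 (0.0583 to 0.0669). Cml3 averaged 1.33 tags per restricted library, Chrna4 2.67 and Treh 3, and Aldh1l2 averaged 3.17 per control library, so the sizes of their fold changes are uncertain. Over the alternatives Treh ran from -3.74 to -1.68 and Aldh1l2 from 1.72 to 3.31. Igf1 had a log2 fold change of -0.59 ± 0.15 with an adjusted p of 0.0572 in edgeR, and Ucp1, Lep and Phgdh had too few tags to be tested, with at most 13, 6 and 6 in a library.

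Of 24 tested genes of the amino acid response in liver, 8 rose and none fell over all genes, and 13 were higher adjusted over the list alone. The 8 included Asns, Aldh1l2, Psat1, the amino acid transporter gene Slc7a5 (1.36 ± 0.18) and Fgf21. Gdf15 and Aldh18a1, also among them, lost their calls without most single libraries (edgeR adjusted p of 0.0526 to 0.0841 and 0.0554 to 0.0824). The list had a median of 0.58 and a camera adjusted p of 1.41e-14, and it was the only list of the 38 called that held with an estimated correlation (adjusted p = 0.0213 with an estimated correlation). Of 28 NRF2 targets, which act in antioxidant defence and conjugation, 8 rose, including the carbonyl reductase gene Cbr1 (1.25 ± 0.16), the epoxide hydrolase gene Ephx1 (1.06 ± 0.15), Aox1 (0.97 ± 0.11) and Gstm1 (0.86 ± 0.10). In contrast 1 fell, Gstm6 (-0.44). Gstm6 lost its call without any single library other than CON3106 or CON3115 or MR3101 (edgeR adjusted p of 0.0618 to 0.0887). Txnrd1 and Gsr, among the NRF2 targets that rose, lost theirs without several single libraries (0.0618 to 0.0828 and 0.0532 to 0.0930). Adjusted over the list alone, 14 were higher and 2 lower (camera adjusted p = 6.54e-08; adjusted p = 0.165 with an estimated correlation). In the methionine and sulfur amino acid list, which did not pass as a list (camera adjusted p = 0.224), 1 of 29 genes rose, Csad, and 1 fell, Dmgdh (-1.05 ± 0.20), which acts in betaine breakdown.

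Of 24 lipogenesis genes in liver, 7 fell and none rose over all genes, and 10 were lower and 1 higher adjusted over the list alone. The 7 included Scd1, Thrsp (-1.79 ± 0.29), the pyruvate kinase gene Pklr (-1.07 ± 0.19) and Acss2 (-0.93 ± 0.14). Acacb and Acly, also among them, lost their calls without several single libraries (edgeR adjusted p of 0.0546 to 0.0706 and 0.0558 to 0.0784). The list had a median of -0.42 (camera adjusted p = 1e-06; adjusted p = 0.292 with an estimated correlation). Of 25 liver genes that are higher in males under growth hormone control, 6 fell, including Cyp4a12b, the urinary protein gene Mup21 (-1.62 ± 0.25), Ugt2b1 (-0.62 ± 0.12) and Cyp4a12a (-0.86 ± 0.17). Selenbp2 and Nudt7 of this list lost their calls without several single libraries (edgeR adjusted p of 0.0626 to 0.107 and 0.0528 to 0.0682). Adjusted over the list alone, 10 were lower and 1 higher (median -0.46; camera adjusted p = 2.02e-07; adjusted p = 0.278 with an estimated correlation). Of 12 liver genes that are higher in females, 2 rose, Cyp4a14 and Cyp39a1, and 5 were higher adjusted over the list alone (median 0.25; camera adjusted p = 0.0206; adjusted p = 0.488 with an estimated correlation). Without CON3106, MR3101 and MR3113 the camera adjusted p of the female list was 0.0528, 0.0593 and 0.0562, and with the blood marker level as a covariate it was 0.153. The median of that list ran from 0.09 without MR3101 to 0.75 with the stricter filter. Hepatocyte markers had a median of -0.20 with 1 of 25 lower over all genes, Serpina3k (-0.81 ± 0.17), and 3 adjusted over the list alone (camera adjusted p = 0.00753; adjusted p = 0.292 with an estimated correlation).

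Of 17 acute phase genes in liver 3 fell, Orm3 (-3.22 ± 0.43), Orm1 (-1.57 ± 0.22) and Saa1. Adjusted over the list alone, 3 were lower and 1 higher (median -0.16; camera adjusted p = 0.0206; adjusted p = 0.325 with an estimated correlation). The acute phase list lost its call without CON3106 (camera adjusted p = 0.0816), CON3107 (0.0656), CON3112 (0.119), CON3115 (0.287) and MR3101 (0.0887) and with the stricter filter (0.186), and Saa1 itself in 7 of 12 fits that left out a library. The matrix list had a median of -0.22 over 27 genes, with Col5a3 lower (-0.59) and Mmp14 higher (0.73). It had 3 genes lower and 1 higher adjusted over the list alone, a camera adjusted p of 0.0164 and an adjusted p = 0.527 with an estimated correlation. It lost its call without CON3107 (camera adjusted p = 0.170) and MR3102 (0.0517). Col5a3 lost its own without any single library other than CON3107 or CON3114 or MR3101 or MR3113 (edgeR adjusted p of 0.0615 to 0.0937), and Mmp14 without CON3103, CON3106 and CON3114 and MR3109, MR3113 and MR3116 (0.0504 to 0.0781). Of 15 heat shock genes 1 rose, Hspb1 (1.12 ± 0.16), and 3 were higher adjusted over the list alone (median 0.13; camera adjusted p = 0.0243; adjusted p = 0.488 with an estimated correlation). The camera adjusted p of that list was 0.0712, 0.0563, 0.0523, 0.0980 and 0.0707 without CON3107, CON3112, CON3115, MR3101 and MR3104. Its median ran from 0.04 without MR3104 to 0.29 without MR3109. Blood markers had a median of -0.57 over 6 genes, led by Alas2 (-0.70), with 0 past the edgeR threshold, 1 lower adjusted over the list alone, a camera adjusted p of 0.0390 and an adjusted p = 0.488 with an estimated correlation. Camera gave 0.0830, 0.0980 and 0.0560 without CON3114, MR3101 and MR3102 and 0.813 with the list's own level as a covariate, and the call was also lost with no filter. The loss with the list's own level was set in advance.

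With the mean level of the blood markers as a covariate, 45 genes were higher and 66 lower in liver, and 97 of the 248 genes called without it were called with it. All 248 kept their direction, with Gstm1, Aox1 and Cbr1 at 0.82, 0.95 and 1.27, Scd1 at -2.76 and Epb4.1l1 at 1.31, and the cause of the lower count was not tested. DESeq2 called 199 and 291 genes and a joint fit over all libraries 14 and 15, and the number higher was 75, 76, 68 and 72 without CON3103, CON3114, MR3109 and MR3113. The tags of Mup21, Cyp4a12a and Cyp4a12b, Orm1 and Orm3, Saa1, Ugt2b1, Cml3 and the Gstm genes come from families of near-identical genes, so the split of counts within each family is uncertain.

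In gastrocnemius, no gene passed the threshold. The lists of slow fibre genes, of lipid metabolism, of adipocyte markers and of the matrix ranked lower under methionine restriction in camera with its preset correlation. These calls were lost with an estimated correlation (camera adjusted p = 0.313 for the slow fibre and matrix lists and 0.488 to 0.512 for the lipid and adipocyte lists). Slow fibre genes had a median log2 fold change of -1.31 over 14 tested genes, with Sln, a regulator of the muscle calcium pump, at -2.96 ± 0.68 (SE, n = 6 and 5) and the slow myosin gene Myh7 at -2.29 ± 0.81. Lep was at -2.69 ± 0.86, Scd1 at -1.53 ± 0.58 and the fatty acid synthase gene Fasn at -2.04 ± 0.78, none past the threshold. Whether these transcripts came from muscle fibres or from adipocytes in the sample was not tested.

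Of 11225 genes tested in gastrocnemius, 0 were higher and 0 lower in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.764), and 709 had an unadjusted p under 0.05, where 561 were expected by chance. DESeq2 called 0 higher and 2 lower, and limma voom 0 and 0 with 123 genes at an unadjusted p under 0.05. The median log2 fold change of all tested genes was -0.04 in edgeR, -0.19 with limma voom, and -0.17 and -0.11 on the authors' normalized counts with pseudocounts of 1 and 8. Changes under these scalings are relative to those medians. MR3101 had a median Spearman correlation of 0.582 to the other gastrocnemius libraries, against 0.928 to 0.955 for the rest, and detected 11144 genes. Asns, Psat1, Igf1 and Ucp1 had log2 fold changes of 0.37, 0.11, -0.30 and 0.10, with edgeR adjusted p-values of 0.971, 0.983, 0.971 and 0.990.

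In the slow fibre list of gastrocnemius, 1 gene, Sln, was lower adjusted over the list alone, and Myl3 was at -2.01 and Tnnc1 at -2.15 (camera adjusted p = 1.84e-07; adjusted p = 0.313 with an estimated correlation). Without MR3101 the median was -1.45 for this list, 0.42 for hepatocyte markers, -0.01 for skeletal muscle markers, -0.02 for immediate early genes, 0.47 for cell cycle genes, -0.40 for white adipocyte markers, -0.44 for adipocyte markers, -0.29 for lipogenesis, -0.32 for lipolysis and lipid uptake and -0.32 for the matrix. Lipogenesis (-0.32), lipolysis and lipid uptake (-0.43) and white adipocyte markers (-0.62) had camera adjusted p-values of 0.0160, 0.00138 and 0.00335, each with an adjusted p = 0.488 with an estimated correlation. Adipocyte markers (-0.52) had a camera adjusted p of 0.00304 and an adjusted p = 0.512 with an estimated correlation. These lists were led by Fasn, Scd1, Cidec (-1.56) and Lep, with Pparg at 1.87 against the direction of the adipocyte list. Pparg had a deviation of 4.204 on the log2 scale in MR3101, the library that stood apart, so its value may rest in part on that library. Lipogenesis lost its call without CON3103 (camera adjusted p = 0.104) and adipocyte markers without MR3104 (0.0741). Over the alternatives the median ran from -0.56 to -0.25 for lipogenesis and from -0.77 to -0.17 for lipolysis and lipid uptake. It ran from -1.36 to -0.37 for white adipocyte markers, from -0.67 to -0.39 for adipocyte markers and from -0.60 to -0.22 for the matrix. The matrix list had a median of -0.43 with Postn at -1.13 (camera adjusted p = 0.000245; adjusted p = 0.313 with an estimated correlation). Hepatocyte markers (1.26, with Apoa1 at 2.58), skeletal muscle markers (-0.30, with Mb at -0.92) and immediate early genes (-0.13, with Egr1 at -1.15) had camera adjusted p-values of 0.000149, 0.00304 and 0.0234, with adjusted p = 0.488, 0.597 and 0.545 with an estimated correlation. Without MR3101 their camera adjusted p-values were 0.0853, 0.421 and 0.0583. With the blood marker level as a covariate they were 0.574, 0.144 and 0.190, with medians of 0.35, 0.22 and -0.01, so the skeletal muscle list changed sign. The blood marker level was itself far lower in MR3101 (-0.956 log2 CPM) than in the next restricted library (1.45), so this covariate may in part stand for MR3101. The immediate early list also lost its call without MR3102 (0.155) and MR3104 (0.105) and with the stricter filter (0.0689). Cell cycle genes had a median of 0.77 with Rrm2 at 1.35 (camera adjusted p = 0.0455; adjusted p = 0.488 with an estimated correlation). Camera gave 0.0833, 0.0632, 0.0749, 0.0565, 0.0688 and 0.435 without CON3103, CON3106, CON3112 and CON3114 and MR3104 and MR3109. It gave 0.0575 with RLE factors and with no filter, 0.0774 on the authors' normalized counts with a pseudocount of 1, where the median was 0.18, and 0.160 with the blood covariate. Lymphocyte markers had a mean of 6.30 log2 CPM in MR3109 and of 1.88 in the next restricted library. No member of these lists other than Sln passed adjusted over the list alone.

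**Figure D3:**
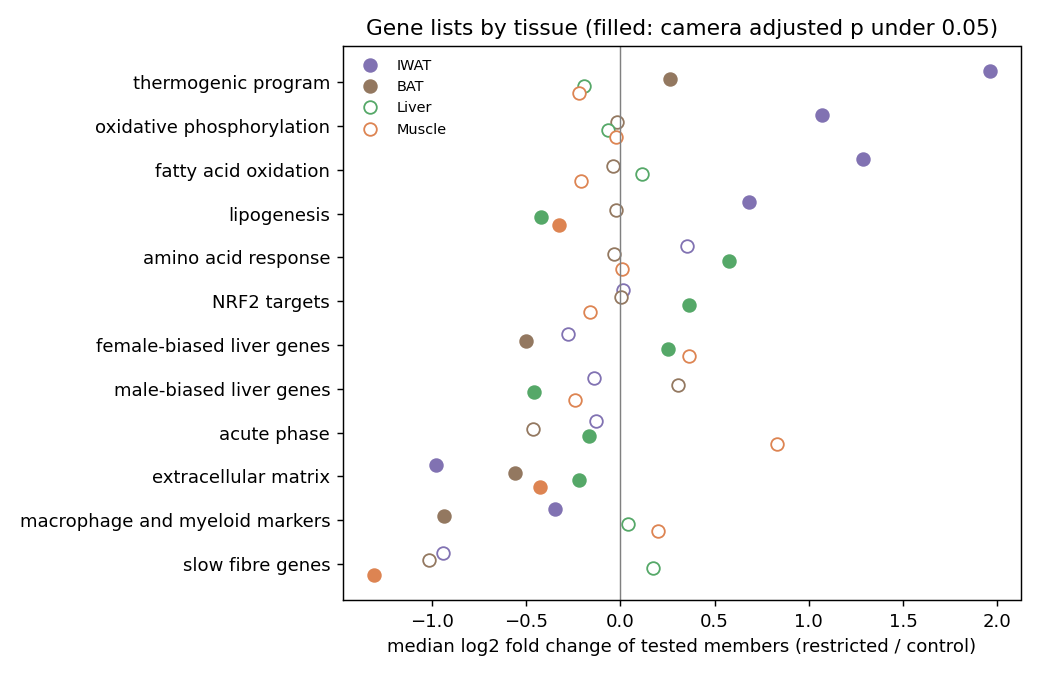
Median log2 fold change of the tested members of 12 gene lists, restricted over control, with a point per tissue, filled where camera with its preset correlation gave an adjusted p under 0.05. The thermogenic list stands at 1.96 in IWAT and 0.27 in BAT, and the amino acid response list at 0.58 in liver.

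The diet effect differed between tissues for single genes. Asns rose in liver with a log2 fold change of 3.36, against 0.35 in IWAT, 0.25 in BAT and 0.30 in gastrocnemius in a joint fit of all 47 libraries. The difference passed the test of the interaction (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0011). Lbp went down in the adipose tissues (-2.80 in IWAT and -1.58 in BAT) and up in liver (0.84; edgeR adjusted p = 5.47e-06). The acute phase gene Orm3 went up in the adipose tissues (1.42 and 1.46) and down in liver (-3.24; edgeR adjusted p = 0.000197). Gyk was higher in IWAT and BAT (3.03 and 1.90) and near 0 in liver (-0.02; adjusted p = 0.000854). Of 13541 genes in this fit, 71 had diet effects that differed among the 4 tissues, 7 between IWAT and BAT, 80 between IWAT and liver and 4 between liver and gastrocnemius. The fit gave each gene the same dispersion in all tissues. Fitted by tissue, the coefficient of variation between animals in edgeR was 0.688 in IWAT, 0.363 in BAT, 0.228 in liver and 0.560 in gastrocnemius. The joint fit may thus understate the spread in IWAT and overstate that in liver, so its calls that involve IWAT may be too many. The other 3 pairs, which the plan kept for named genes only, gave 59 for IWAT and gastrocnemius, 14 for BAT and liver and 0 for BAT and gastrocnemius in edgeR (1826 genes at an unadjusted p under 0.05), and their counts were not relabelled.

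The 6 genes with the smallest adjusted p over the 4 tissues were Lbp, Orm3, Gyk, the bicarbonate transporter gene Slc4a4 (2.49 in IWAT, 1.20 in BAT, 0.51 in liver and -0.17 in gastrocnemius), Cyp39a1 (2.14 in liver, -0.26 in IWAT and -0.43 in BAT) and Asns. Of list members among the leading 100 genes, the fatty acid oxidation genes Hadhb (2.05 in IWAT, -0.22 in BAT), Acadvl (1.95 and 0.05) and Slc25a20 (1.72 and -0.13) and the thermogenic gene Letmd1 (2.10 and -0.12) were highest in IWAT. The difference between IWAT and BAT itself passed for Hadhb (edgeR adjusted p = 0.0135) and Letmd1 (0.0233) and not for Acadvl or Slc25a20 (0.0726 each). These calls rest on the dispersion shared by all tissues. For Acadvl the SE of the difference was 0.450, against 0.455 for the diet effect in the fit of IWAT alone. Without CON3103 the test of IWAT against BAT called 1 gene in all, so Hadhb and Letmd1 were not both called there. Ppargc1a (1.26, 0.79, 0.11 and -0.43 in the order IWAT, BAT, liver and gastrocnemius) and Dio2 (2.08 and 1.33 in IWAT and BAT) differed among the 4 tissues. So did Elovl3 (3.46, 1.44 and -0.44 in IWAT, BAT and liver), Acot11 (2.62 and 0.37 in IWAT and BAT) and Gpam (1.54, 1.30 and -0.43 in IWAT, BAT and liver). Cyp2u1 was at 2.84 in IWAT, and Psat1 (2.97), Aldh1l2 (3.14) and Cyp4a14 (2.87) were highest in liver.

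Many of these calls over the 4 tissues were lost when an animal was left out of the joint fit. Gpam (edgeR adjusted p of 0.0511 to 0.0614) and Acadvl (0.0607 to 0.0928) were lost without MR3109, CON3112 or CON3115. Hadhb (0.0570 to 0.131) was lost without these or CON3107, and Letmd1 (0.0597 or more) also without CON3103. Ppargc1a was lost without MR3101, CON3103, CON3106, MR3109 or CON3112 (edgeR adjusted p of 0.0586 to 0.0947), and Cyp4a14 without MR3101, CON3103, MR3109, CON3112 or MR3113 (0.0533 to 0.159). Dio2 was lost without MR3101, MR3102, CON3103, MR3109, CON3112 or CON3115 (edgeR adjusted p of 0.0501 to 0.115). Elovl3 (0.0614 to 0.114) and Acot11 (0.0756 to 0.135) were lost without MR3101, MR3102, MR3104, CON3106, MR3109, CON3112, MR3113 or CON3115. Cyp2u1 was lost without these except MR3104 and also without CON3103 (edgeR adjusted p of 0.0659 to 0.131). Slc25a20 was lost without any animal other than MR3101, MR3104 or CON3114 (0.0586 to 0.175). The 6 leading genes, Aldh1l2 and Psat1 were called without any single animal.

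With the animal as a block, 41 genes differed among the 4 tissues and 1 between liver and gastrocnemius. In that fit Cyp4a14 (edgeR adjusted p = 0.223), Slc25a20 (0.0774), Letmd1 (0.0605), Hadhb (0.0593) and Cyp2u1 (0.0593) lost their calls. Limma voom called 151, 39, 130 and 7 genes in the tests of the 4 tissues, IWAT against BAT, IWAT against liver and liver against gastrocnemius. Leaving out the 4 libraries that stood apart, a choice made after seeing the data, gave 259, 66, 236 and 17. Of 100 assignments of the diets to the animals, the real one included, 20 gave as many genes over the 4 tissues. With whole animals left out, the count over the 4 tissues was 38 without MR3101, 34 without MR3102, 45 without CON3103, 32 without CON3106, 236 without CON3107, 30 without MR3109, 24 without CON3112, 43 without MR3113, 116 without CON3114, 23 without CON3115 and 847 without MR3116. Between IWAT and BAT it was 1 without CON3103, 221 without CON3107, 2 without MR3109 or CON3112, 65 without CON3114, 3 without CON3115 and 13 without MR3116. Between IWAT and liver it was 34 without MR3102 or CON3115, 46 without MR3104 or MR3109, 30 without CON3106, 36 without CON3112, 33 without MR3113 and 135 without CON3114. Between liver and gastrocnemius it was 2 without CON3107, 1 without CON3103, MR3104, CON3106 or MR3116, and 0 in edgeR without MR3102, MR3109, CON3112, MR3113 or CON3114.

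Genes called in more than 1 tissue were few. Acss2, Scd1, Sucnr1, a receptor for succinate, and Hnmt, which inactivates histamine, fell in BAT and in liver, and Lbp fell in IWAT and BAT and rose in liver (0.86; edgeR adjusted p = 0.0273). Orm3 rose in BAT (1.44 ± 0.21) and fell in liver (-3.22 ± 0.43), and Epb4.1l1 fell in BAT (-1.05 ± 0.16) and rose in liver (1.85 ± 0.35), so 3 genes were called in opposite directions in BAT and liver and 1 in IWAT and liver. The 4 genes lower in both BAT and liver compare with 0.276 expected for independent lists, and 0 genes were higher in both in edgeR, with 0.344 expected. No gene was called in the same direction in 3 tissues in these fits. With the term for the 3 IWAT libraries, chosen after seeing the data, Sucnr1 was lower in IWAT (-1.23), BAT (-1.68) and liver (-1.18). Across genes, which are not independent replicates, the log2 fold changes of IWAT and BAT had a Pearson correlation of 0.279 and a Spearman correlation of 0.236 over 10259 genes. The other 5 pairs of tissues had Pearson correlations between -0.105 and 0.067.

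The 5 genes that shared a direction in 2 tissues depended on the threshold, the tool and the animals. Their number became 12 at an adjusted p under 0.1, 0 at 0.01 in edgeR, and 60 with DESeq2. It was 2 without MR3101, MR3102, CON3103 or CON3112, 3 without CON3106, CON3107, MR3109, MR3113, CON3115 or MR3116, 0 without MR3104 and 5 without CON3114. Hnmt lost its call in liver without any single library other than CON3106 (edgeR adjusted p of 0.0512 to 0.0911) and in BAT without any other than CON3115 or MR3102 or MR3109 (0.0542 to 0.0827). Sucnr1 lost its call in BAT without MR3101, MR3104 and MR3113 (edgeR adjusted p of 0.0525 to 0.0636). Lbp lost its call in BAT without MR3104 (0.0542) and in liver without CON3103, CON3106, CON3107 and CON3114 and MR3104, MR3109, MR3113 and MR3116 (0.0534 to 0.0698). Camera called 38 of 116 list tests, and fry, run on the same values, called 10.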

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

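Of the tests in this part, those of tag GC content, of library depth and of muscle transcripts as the maker of the BAT calls were chosen after the result was seen.

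In groups of 4 to 10 libraries, a library was picked out when its gap to the nearest other library was large against the range of its group, which chance gives in about 1 of 20 groups. This held in 20 of 146 groups, where 7.3 are expected by chance. In IWAT, CON3112 had a total of 4.887 (in units of 1e+06 counts; next 6.338), and MR3116 had 11917 detected genes (next 14685) and a median Spearman correlation of 0.647 (next 0.903). In gastrocnemius, MR3101 had 11144 detected genes (next 14676) and a correlation of 0.582 (next 0.928). Mean levels of marker lists in log2 CPM stood out for lymphocytes in IWAT CON3107 (7.015; next 2.167) and gastrocnemius MR3109 (6.296; next 1.88), and for skeletal muscle in liver CON3114 (5.525; next 2.782) and gastrocnemius MR3101 (6.966; next 11.522). They stood out for blood in IWAT MR3116 (-0.102; next 1.965), BAT CON3115 (1.788; next 2.226) and gastrocnemius MR3101 (-0.956; next 1.45), and for hepatocytes in IWAT MR3113 (7.707; next 4.467) and BAT CON3106 (7.375; next 3.905). Of named genes in log2 CPM, in BAT Gmpr was 9.415 in MR3116 (next 8.33), Sgk2 3.561 in MR3109 (next 2.4), Myrip 0.151 in CON3103 (next 1.64), Hspa12a 0.685 in CON3114 (next 1.522) and Chn1 7.076 in CON3107 (next 6.263). In liver, Vil1 was -1.03 in CON3103 (next 0.102).

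For 19 named genes the diet effect differed among the 4 tissues by the interaction test itself, and the value given is the range of the log2 fold changes over the tissues. As many genes were called in 20 of 100 assignments of the diets to the animals. The range takes in all tissues, also one with few tags of the gene, so its size can be uncertain. Dio2 was at -1.26 in liver, where it was not tested in the fit of that tissue. Aldh1l2 and Cyp4a14 were at -2.37 and -2.21 in IWAT. The range was 5.517 for Aldh1l2, 5.081 for Cyp4a14, 4.701 for Orm3, 3.899 for Elovl3, 3.642 for Lbp, 3.605 for Psat1, 3.54 for Acot11, 3.337 for Dio2, 3.119 for Cyp2u1, 3.103 for Asns and 3.047 for Gyk. It was 2.666 for Slc4a4, 2.57 for Cyp39a1, 2.426 for Acadvl, 2.271 for Hadhb, 2.215 for Letmd1, 1.97 for Gpam, 1.848 for Slc25a20 and 1.684 for Ppargc1a.

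CON3106, CON3115 and MR3116 in IWAT and MR3101 in gastrocnemius stood apart, and over 10199 genes the mean deviation of the 3 correlated with that of the 1 at 0.882. A mislabelled tissue is argued against, since each library correlated better with its own tissue (largest difference -0.045), and so is library depth, since 2 of the 4 lay above the median total of their tissue. RNA from another cell type is argued against only for the 3 IWAT libraries, where the adipocyte markers had a median deviation of -0.091 (SD 3.21 over 20 markers) while 943 genes fell below -4 and 0 rose above 4, and it was not tested for MR3101. The GC content of the tag had the values it needs, since 0 other IWAT or gastrocnemius libraries had as low a correlation of deviation and tag GC as the weakest of the 4, so a technical loss that follows GC content may be a cause. The tag is not singled out, since the correlation was stronger with GC content of the transcript end (-0.599 to -0.551) than with that of the tag (-0.485 to -0.447) and was -0.503 to -0.440 with distance to the 3' end, the 3 together left most of the spread open (R squared of 0.400 to 0.428), and no biological explanation was tested.

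Skeletal muscle markers ranged widely among BAT libraries. Over the 25 markers, all of them tested in BAT, the excess in 8 libraries over the 4 lowest followed the level in gastrocnemius with a Spearman correlation of 0.909, so RNA from another cell type, muscle next to the fat pad, may be its source, at a median of 5.69 percent of the gastrocnemius level. Ckm averaged 2970 CPM in control BAT and 84521 in control gastrocnemius, and Mylpf 839 and 18802. With the muscle list as a covariate, 118 of the 120 BAT calls were kept, which argues against muscle RNA as what made the BAT calls. Whether the muscle transcripts come from dissection or from the tissue itself was not tested.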

How the results depend on the processing

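Of the tests in this part, those that leave out or model the libraries that stood apart, those that leave out an animal other than MR3113 from the joint fit or any animal from the shared count, and the Spearman correlations were chosen after the result was seen. The causes of the changes below were not tested.

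In IWAT, where 1 gene was higher and 2 lower, the counts were 266 and 180 with 1 fit over all libraries, 168 and 142 with DESeq2, 5 and 2 with limma voom, 3 and 3 with upper-quartile factors and 2 and 2 with the stricter filter. They were 9 and 5, and 10 and 10, on the authors' normalized counts with pseudocounts of 1 and 8. With covariates they were 565 and 478 (blood markers), 7 and 6 (lymphocyte markers) and 2 and 7 (skeletal muscle markers). They were 0 and 0 in edgeR without the 3 libraries that stood apart (1826 genes at an unadjusted p under 0.05) and 315 and 305 with a term for them. Without any 1 library they ranged from 0 to 28 and from 0 to 13.

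In BAT (62 and 58), they were 22 and 19 with 1 fit over all libraries, 165 and 152 with DESeq2, 94 and 97 with the skeletal muscle covariate, and 25 to 53 and 25 to 60 without any 1 library. In liver (115 and 133), they were 14 and 15 with 1 fit over all libraries, 199 and 291 with DESeq2, 45 and 66 with the blood covariate, and 68 to 145 and 90 to 177 without any 1 library. In gastrocnemius (0 and 0), DESeq2 called 2 lower, and edgeR called 0 and 0 without any 1 library. Of the 120 BAT calls, DESeq2 kept 120, limma voom 116 and 1 fit over all libraries 22. Of the 248 liver calls these kept 248, 227 and 28.

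For genes whose diet effect differs between the 4 tissues (71), the replicate block gave 41, limma voom 151, limma voom with the block 134, the fit without the 4 libraries that stood apart 259, and leaving out an animal 23 to 847. Between IWAT and BAT (7), these were 39 with limma voom, 36 with the block added, 66 without the 4 libraries and 1 to 221 without an animal. Between IWAT and liver (80), they were 130 with limma voom, 236 without the 4 libraries and 30 to 135 without an animal. Between liver and gastrocnemius (4), the replicate block gave 1, limma voom 7, limma voom with the block 7, the fit without the 4 libraries 17, and leaving out an animal 0 to 5. With the replicate block the counts were 5 between IWAT and BAT and 59 between IWAT and liver, within the 1.5-fold range taken as unchanged. The edgeR block adds a term for each animal, so a lower count with it is not by itself an effect of the pairing.

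Of 38 lists called by camera, 1 was called with an estimated correlation and 10 with fry, and 35 to 39 without any 1 library. Skeletal muscle markers in gastrocnemius changed sign with the blood covariate (median 0.22). The count of 5 genes called in the same direction in more than 1 tissue was 0 at an adjusted p under 0.01, 12 at 0.1, 60 with DESeq2, 45 with the IWAT term, and 0 to 5 without an animal. The correlations of diet effects moved by less than 1 SD of the relabelled values under each alternative run, although that of IWAT and gastrocnemius went from -0.085 to 0.081, and that of liver and gastrocnemius from -0.009 to 0.04, without the 4 libraries that stood apart.

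Of the values of single called genes under the alternatives, 1876 were on the same side of the threshold and 382 no longer passed. Of uncalled ones, 2898 stayed and 172 came to pass, and 40 of 2889 values uncalled in both changed sign. For called lists, 688 values stayed and 74 no longer passed. List tests were not run with DESeq2, with limma voom as a separate setting, or with 1 fit over all libraries.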

Other observations

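The tests in this part were chosen after the result was seen, except the relabellings of animals for genes called in the same direction in more than 1 tissue and for correlations of diet effects, which were planned, with only their threshold set afterwards.

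With a term for the 3 IWAT libraries that stood apart, 315 genes were higher and 305 lower in IWAT in edgeR. Ucp1 rose by 3.08 ± 0.55 on the log2 scale (adjusted p = 0.0111), from 181 ± 188 to 1603 ± 520 CPM (SD, n = 6 and 6), with Elovl3 (3.28; 0.00611), Slc4a4 (2.62; 0.00188), Ppp1r3b (2.42; 0.00605) and Acot11 (2.41; 0.0125). Lep fell by 3.13 ± 0.36 (adjusted p = 0.00188), from 407 ± 379 to 62.2 ± 37.8 CPM, with Sfrp5 (-3.55; 0.00572), Npr3 (-2.65; 0.00637), Lbp (-2.65; 0.00188) and Mest (-2.35; 0.0179). Without MR3116 the counts fell to 6 higher and 15 lower and Ucp1 had an adjusted p of 0.0802, and without any other library the total was 183 (CON3112) to 751 (CON3114). Of lists, 14 of 22 thermogenic genes were higher (17 higher and 1 lower over the list alone; median 1.90; camera adjusted p = 3.68e-17; adjusted p = 0.262 with an estimated correlation). Of 45 oxidative phosphorylation genes, 17 were higher and 1 lower (29 and 1 over the list alone; median 0.91; camera adjusted p = 1.78e-20; adjusted p = 0.315 with an estimated correlation). Of 27 fatty acid oxidation genes, 8 were higher (14 higher and 2 lower over the list alone; adjusted p = 0.421 with an estimated correlation), and the median was 0.83 against 1.29 without the term. Of 32 matrix genes, 14 were lower (25 over the list alone; median -0.98; camera adjusted p = 2.5e-16; adjusted p = 0.262 with an estimated correlation). Under this fit IWAT and BAT shared 18 higher genes (1.72 expected for independent lists) and 15 lower genes (1.43 expected), and 1 was opposite.

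The few genes called in IWAT without the term may come from the spread from the 3 libraries that stood apart, which cannot be told apart from other causes here. The term gave 315 and 305 genes, while leaving the 3 out gave 0 in edgeR, with 1826 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.054. The coefficient of variation between animals in edgeR was 0.688 with all libraries and 0.419 without the 3. What keeps it open is that leaving them out also left 4 control and 5 restricted libraries.

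The diets were reassigned to whole animals in 100 ways, the real assignment included, to see whether chance can be excluded at a share under 0.05. As many genes were called in 1 of 100 assignments in IWAT (real 3, highest other 0), 1 in BAT (120; 1), 1 in liver (248; 40) and 100 in gastrocnemius (0; 0), and in 1 with the IWAT term (620; 217). No other assignment reached the real count in IWAT, BAT or liver, which argues against chance there. The share of 1 of 100 is the smallest that 100 assignments can give and was not adjusted for the number of counts compared. In IWAT without the term it rests on 3 genes, whose calls were lost without most single libraries. In gastrocnemius the real count of 0 fixed the outcome in advance, so it says nothing about chance. For lists called over the 4 tissues it was 2 of 100 (38; 39), with a median of 21 lists over the other 99, so a single called list is weak evidence. By tissue it was 22 in IWAT (9; 16), 15 in BAT (9; 12), 10 in liver (10; 12) and 2 in gastrocnemius (10; 11). Chance is not excluded for the lists of IWAT, BAT or liver. The shares for the 4 tissues together and for gastrocnemius were under 0.05, but in each case another assignment called more lists. These shares were not adjusted for the number of counts compared, so they do not settle whether the gastrocnemius lists arose by chance.

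For genes called in the same direction in more than 1 tissue it was 1 of 100 (5; 0). No other assignment called genes in more than 1 tissue, so none could give a shared gene, and this share cannot exclude chance for the sharing. For the size of the correlation of the diet effects of IWAT and BAT it was 3 of 100 (0.279; 0.370). The other 5 pairs of tissues gave 57, 97, 68, 47 and 86 of 100. As the smallest of these shares, not adjusted for the number of pairs, 3 of 100 does not exclude chance. For the interaction it was 20 of 100 over the 4 tissues (71; 1673), 15 for IWAT against BAT (7; 1207), 1 for IWAT against liver (80; 5) and 1 for liver against gastrocnemius (4; 3). Without the 4 libraries that stood apart it was 4 (259; 612), 18 (66; 746), 1 (236; 127) and 1 (17; 6). The share was under 0.05 for the last 2 tests in both versions, and for the 4 tissues only without the 4 libraries, a choice made after seeing the data. For IWAT against BAT it was not. Reassigning whole animals takes the diet effect out of every tissue at once. These shares therefore do not test whether an existing effect is equal between tissues. Liver against gastrocnemius rested on 4 genes, with 1 under the animal block and as few as 0 with an animal left out. Assignments that called several times the real number point to a structure of the samples that is not the diet, and which animals carry it was not tested.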
